A study of Homo sapiens with 18 samples.

How the data were processed

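MCF-7aro cells are a derivative of the MCF-7 human breast cancer line that carries aromatase, the enzyme that turns androgens into estrogens. Total RNA of 18 cultures or samples of these cells was hybridised to Affymetrix Human Genome arrays of the type HG-U133 A, 1 array each, in 6 groups of 3: untreated control, androgen, estrogen, and androgen together with letrozole, anastrozole or tamoxifen. Group and replicate number came from the sample titles. The labels give no dose, duration or medium, and do not say whether replicates were separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

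The deposited table holds 22283 probe sets. Its values are intensity on a linear scale, from 18.6 to 25709, made by the authors. The method that summarised the probes and scaled the arrays is not given in the sources used here. The values had already been made comparable between arrays: array medians lay between 175 and 182, or 7.45 and 7.51 on the log2 scale, within the tolerance of 0.1 set for keeping the authors' normalization. All 18 value columns belonged to samples of the series. Each array's experiment file was used only for the scan day, taken as a batch and numbered 1 to 4.

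From these values, log2(intensity + 67) was computed, where 67 is the 20th percentile of all values. Fold changes are on that scale and understate changes of dim genes. The 68 control probe sets were set aside, 18 of them bacterial and phage spike-ins used only to describe batches. Of the others, 19065 had 1 gene symbol in the platform annotation, 1043 had several and 2107 had none. Symbols were looked up by Entrez identifier in RefSeq's gene table (GRCh38.p14), which matched 19053 probe sets and changed 0 symbols. Each of 11963 genes was represented by the probe set with the highest mean, and by a probe set ending in _x_at only where it had no other. A total of 4310 genes had more than 1 probe set. The lowest 30% of genes by mean were left out, and 8374 were tested. Signal over background, not read depth, bounds what such arrays can detect, and 3 arrays per group limit the precision: the median half-width of a 95% interval was 0.32 log2 units in each comparison.

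Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). All 18 arrays entered a single model of the 6 groups, with 12 residual degrees of freedom and no block. Where arrays of different groups share deviations, such a fit counts these as spread and can miss differences. In each comparison fewer genes had an unadjusted p under 0.05 than the 419 of chance. The p-values were adjusted by the Benjamini-Hochberg method within each of 12 comparisons, and a gene passed at an adjusted p under 0.05. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over 21 lists within a comparison, and again with an estimated correlation and with fry, which asks whether a list's own genes move one way on balance. The lists cover estrogen-induced and estrogen-repressed genes, androgen receptor targets, DNA replication and G1/S, mitosis, cell cycle inhibitors and p53 targets, apoptosis regulators, ribosome biogenesis, cholesterol biosynthesis, steroid metabolism enzymes, and steroid receptors and coregulators. They also cover growth factor signalling, unfolded protein and amino acid stress, interferon response, xenobiotic response, hypoxia and glycolysis, immediate early genes, luminal epithelial markers, basal and mesenchymal markers, fibroblast and leukocyte markers, and housekeeping genes.

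The lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. For each of the 5 comparisons against control or androgen, the rule named up to 10 genes in each direction, by fold, among those that passed with no overlap between the arrays of the groups. To these it added, for each list, the member of lowest p or up to 4 members that passed, and 11 preset genes; the text gives those of the lists it describes. For the other 7 comparisons it named up to 5 genes in each direction, or the 3 of lowest p where none passed. Genes that pass only over a list alone, or are described as having the lowest p in a comparison against control or androgen, were named after their values were seen. Calls over a list alone are adjusted within that list and comparison and not over the 21 lists, so some can come by chance.

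The limma fit without a block, and camera at the preset correlation, were tested on simulated values before use. Blocks, fry, the estimated correlation and the correlations across genes were not. The simulated noise was independent between arrays and genes, with no batches and the same spread in every group. Recovery from the real arrays may therefore be lower. With 200 genes changed among 8374, between 82% and 88% of 2-fold and between 97% and 99% of 4-fold changes were recovered in the 5 comparisons against control or androgen, with 4 to 16 false calls each. Pairs of arrays correlated between 0.922 and 0.993, and the closest pair still differed by a median of 0.09 log2 units, so none looked like a repeat deposit. Scan day was nearly balanced over groups (anastrozole replicate 1 was alone on day 2), so it left most log2 changes as they were when fitted as a block. A list call that stays with this block is therefore little further support. In comparisons with anastrozole the block also takes out replicate 1, so it is no separate check from leaving that array out. List medians within days 1, 3 and 4 are given where lists are described.

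Alternatives tried were quantile normalization, centring of array medians, pseudocounts of 1 and of 132 (the 40th percentile), no filter or a 50% filter on dim genes, the mean of a gene's probe sets, and every probe set. Further ones were a fit without the trend, a robust fit, a 2-fold minimum, a fit to only the 6 arrays compared, the replicate number or scan day as a block, and each array left out. A block for 3 clusters of arrays by spike-in level was added after seeing the data, as were the scan day block and the omission of each array for gene lists. Pseudocounts and normalization can change which probe set represents a gene, so these alternatives were also fitted on the same probe sets, which was added after seeing the data; a pseudocount of 1 changed the probe set of 2 tested genes. Leaving out an array leaves 2 in its group, whose spread is then largely taken from the other groups. Figures were drawn with matplotlib 3.10.9.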

Results

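The arrays measured the transcriptome of MCF-7aro breast cancer cells in 6 states, 3 arrays each. Letrozole and anastrozole are non-steroidal triazole inhibitors of aromatase, and tamoxifen is a selective modulator of the estrogen receptor. The questions were what androgen and estrogen change in these cells, and which of those changes each drug opposes when given with androgen. Signals below are linear intensities, given as mean ± SD (n = 3), and changes are log2 differences with the standard error of the limma fit. Median signal per array was between 175 and 182. Aromatase itself (CYP19A1) had a signal of 86.6, too dim to be tested, and the androgen receptor had no named probe set here. Across groups the mean log2 value ranged from 11.29 to 11.43 for luminal markers, from 8.07 to 8.23 for basal and mesenchymal markers and from 8.04 to 8.11 for fibroblast and leukocyte markers; levels of different probe sets cannot be set against each other, so these values do not type the cells.

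Androgen raised the known estrogen-induced genes as a group over control. Of 35 measured members 33 were higher, with a median change of 0.48 log2. The scaffold protein gene PDZK1 went from 362 ± 454 to 1920 ± 285 (log2 2.74 ± 0.66), the transcription factor MYBL1 from 201 ± 188 to 762 ± 184 (1.82 ± 0.38), the progesterone receptor PGR from 64.1 ± 30.6 to 228 ± 91.8 (1.15 ± 0.32), and the secreted trefoil peptide TFF1 from 7610 ± 4150 to 15200 ± 1770 (1.12 ± 0.37). Changes were 0.92 for GREB1, 0.79 for the chemokine CXCL12, 0.48 for cyclin D1 (CCND1), −0.11 for MYC, 0.18 for the proliferation marker MKI67 and −0.32 for the estrogen receptor ESR1. None of these genes passed by itself over all genes.

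The list of estrogen-induced genes passed in androgen against control with camera (adjusted p = 1.0e-23), with an estimated correlation (adjusted p = 0.015) and with fry (adjusted p = 0.038). Adjusted over the list alone, 4 members passed: MYB, MYBL1, PDZK1 and PGR. With scan day as a block the adjusted p was 7.6e-26, and the list median was 0.22, 0.73 and 0.44 within days 1, 3 and 4 and 0.70, 0.19 and 0.44 within spike-in clusters 1, 2 and 3, a grouping chosen after seeing the data. Over all 8374 genes, 0 passed with limma, while 298 had an unadjusted p under 0.05 where 419 would by chance. Without control replicate 1, whose estrogen-induced genes lay closer to the hormone-treated arrays, 22 genes passed, among them PDZK1 (3.58, adjusted p = 0.014), MYBL1 (0.0063), MYB (0.042) and CXCL12 (0.018). Leaving out any other control or androgen array gave 0. Omitting the control array nearest to the treated arrays on these genes favours such calls in advance, so they are no separate support. With scan day as a block 1 gene passed, MYBL1 (adjusted p = 0.034), and with a spike-in cluster block 0 did. Deviations of androgen and control arrays correlated at a mean of 0.63 by cluster and −0.10 by replicate number.

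Several other groups shifted with androgen at the preset correlation only. Estrogen-repressed genes fell as a group (10 of 12 lower, median −0.30, adjusted p = 2.4e-04; adjusted p = 0.23 with an estimated correlation). Among them was the pro-apoptotic gene BIK (255 ± 34 to 126 ± 17.8), which was the 1 member to pass adjusted over the list alone. Mitotic genes rose (31 of 31 higher, median 0.29, adjusted p = 3.0e-12; adjusted p = 0.29 with an estimated correlation), as did DNA replication genes (30 of 36, median 0.11, adjusted p = 0.014; adjusted p = 0.75 with an estimated correlation) and cholesterol biosynthesis genes (15 of 16, median 0.25, adjusted p = 1.3e-06; adjusted p = 0.17 with an estimated correlation). Interferon response genes fell (18 of 18 lower, median −0.29, adjusted p = 9.7e-05; adjusted p = 0.37 with an estimated correlation). Within days 1, 3 and 4 the medians were 0.05, −0.73 and −0.15 for estrogen-repressed genes, −0.33, 0.88 and 0.26 for mitosis, −0.60, 0.75 and 0.21 for DNA replication, 0.09, 0.34 and 0.30 for cholesterol biosynthesis, and −1.36, 0.47 and −0.39 for the interferon response. Within spike-in clusters 1, 2 and 3, which group these arrays otherwise than the scan day, they were −0.45, −0.17 and −0.15, 0.60, −0.06 and 0.26, 0.21, −0.11 and 0.21, 0.43, 0.08 and 0.30, and −0.00, −0.67 and −0.39 in the same order. Cholesterol biosynthesis thus held its direction in both groupings, and estrogen-repressed genes and the interferon response turned by day but not by cluster. Among the members of lowest p were the separase inhibitor PTTG1 (0.51, mitosis), NSDHL (0.26, cholesterol biosynthesis), the interferon-induced gene IFIT2 (−0.25) and cyclin E1 (CCNE1, −0.39), the last lower although most of its DNA replication list was higher; none passed. With scan day as a block the 5 lists passed, with adjusted p from 1.2e-11 to 0.012. This is little support, since deviations of androgen and control arrays did not follow the replicate number (mean −0.10), which for them follows the scan day. For the same reason, the medians within days and their turns in direction may set unlike batches against each other.

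Single arrays carried part of these group shifts. The mitosis call was lost without control replicate 2 (adjusted p = 0.052), the interferon call without control replicate 1 (0.14), and the call for estrogen-repressed genes without androgen replicate 2 (0.055). DNA replication was lost without androgen replicate 2 (0.84), control replicate 2 (0.71) or control replicate 3 (0.51). A further 4 lists, all lower, passed at the preset correlation: xenobiotic response (median −0.17, adjusted p = 0.29 with an estimated correlation), growth factor signalling (−0.12, 0.17), steroid receptors and coregulators (−0.14, 0.32) and luminal epithelial markers (−0.17, 0.29). In the first of these CYP1A1, a detoxifying P450, went from 235 ± 59.4 to 125 ± 14, passing adjusted over the list alone. Each of these 4 calls was lost without at least 3 of the 6 arrays, among them control replicate 2 in every case (adjusted p = 0.074, 0.074, 0.56 and 0.27 in that order). Adjusted over their own lists, apolipoprotein D (APOD, −1.66) and the hyaluronan receptor CD44 (0.52) passed although their lists did not.

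Estrogen produced the same kind of profile. Of the 35 estrogen-induced genes 34 were higher than in control, by a median of 0.53. PDZK1 reached 2050 ± 578 (2.79 ± 0.66), MYBL1 801 ± 177 (1.89 ± 0.38), PGR 224 ± 43.7 (1.16 ± 0.32) and TFF1 15800 ± 2650 (1.17 ± 0.37). GREB1 (1.05), CXCL12 (0.74) and CCND1 (0.53) were higher and BIK was lower (115 ± 28.5, −0.83 ± 0.16), while MYC (0.07) and MKI67 (0.18) differed by less than their standard errors of 0.51 and 0.27, and ESR1 was at −0.37 ± 0.31. Adjusted over the list alone, 17 estrogen-induced genes passed, including PDZK1, PGR, TFF1, GREB1, CXCL12, CCND1 and the lysosomal protease CTSD.

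**Figure D1:**
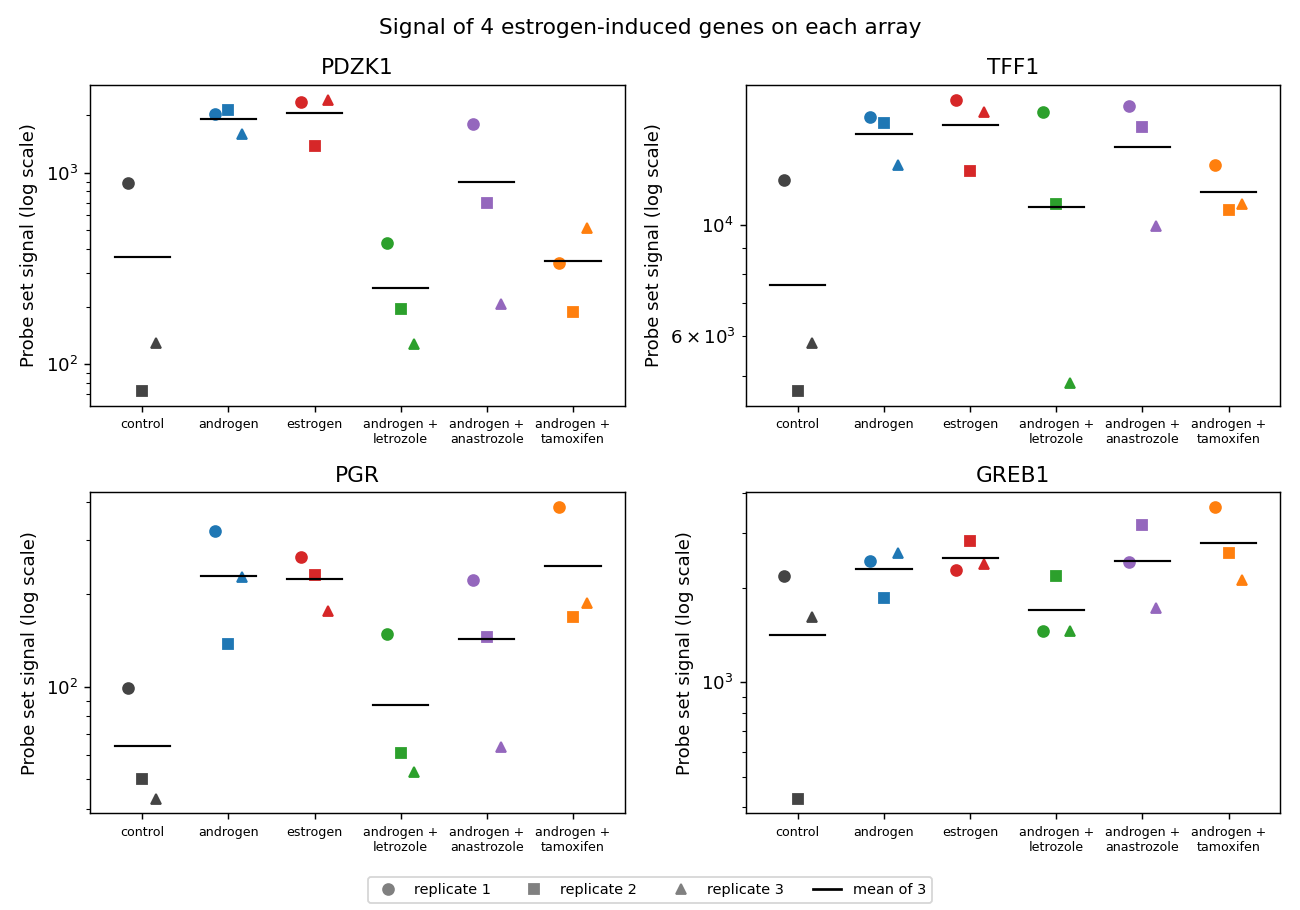
Signal (linear intensity, log axis) of PDZK1, TFF1, PGR and GREB1 on each of the 18 arrays by group; points are arrays and lines are means of 3. PDZK1 was 885 on control replicate 1 and 72.1 and 129 on the other control arrays, against at least 1380 on every androgen or estrogen array.

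For estrogen against control, the estrogen-induced list passed with camera (adjusted p = 3.8e-23), with an estimated correlation (adjusted p = 0.016), with fry (adjusted p = 0.022) and with scan day as a block (adjusted p = 2.6e-25). Its medians were 0.20, 0.70 and 0.59 within days 1, 3 and 4 and 0.89, 0.32 and 0.50 within spike-in clusters 1, 2 and 3. Over all genes 0 passed with limma and 359 had an unadjusted p under 0.05, with BIK and MYBL1 lowest (adjusted p = 0.38). Without control replicate 1, 79 genes passed, among them APOD (−2.74), PDZK1 (3.64), MYBL1 (2.43) and the mTOR inhibitor DEPTOR (1.21, adjusted p = 0.0026). Leaving out any other control or estrogen array gave 0, and omitting the control array nearest to the treated ones favours such calls in advance. A scan day block gave 3: MYBL1 (adjusted p = 0.022), BIK (0.049) and PGR (0.049). A spike-in cluster block gave 0, and deviations of estrogen and control arrays correlated at a mean of 0.60 by cluster and −0.32 by replicate number.

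Other lists again passed at the preset correlation alone in estrogen against control. Estrogen-repressed genes fell (10 of 12, median −0.32, adjusted p = 1.4e-04; adjusted p = 0.15 with an estimated correlation), with BIK and TGFB3 past the threshold adjusted over the list alone. Mitosis rose (31 of 31, 0.37, adjusted p = 5.7e-18; adjusted p = 0.15 with an estimated correlation). The spindle assembly factor TPX2 (0.46) had the lowest p in that list and did not pass. DNA replication rose (34 of 36, 0.25, adjusted p = 9.5e-06; adjusted p = 0.49 with an estimated correlation), a call lost without control replicate 2 (0.13). Cholesterol biosynthesis rose (15 of 16, 0.30, adjusted p = 1.6e-07; adjusted p = 0.15 with an estimated correlation), with INSIG1 and MSMO1 passing adjusted over the list alone. The interferon response fell (18 of 18, −0.26, adjusted p = 4.0e-04; adjusted p = 0.46 with an estimated correlation), a call lost without control replicate 1 (0.24). Medians within days 1, 3 and 4 were 0.10, −0.30 and −0.68 for estrogen-repressed genes, −0.10, 0.78 and 0.51 for mitosis, −0.40, 0.50 and 0.59 for DNA replication, 0.13, 0.30 and 0.39 for cholesterol biosynthesis and −1.28, 0.30 and −0.25 for the interferon response. In clusters 1, 2 and 3 they were −0.51, −0.09 and −0.25, 0.83, 0.02 and 0.36, 0.50, −0.07 and 0.28, 0.62, 0.05 and 0.33, and −0.01, −0.45 and −0.38 in that order. Blocked by scan day, these 5 adjusted p lay between 6.9e-17 and 1.7e-04. Deviations of estrogen and control arrays did not follow the replicate number (mean −0.32), so that block and the medians within days are a weak check. Androgen receptor targets (median −0.07, led by APOD at −1.84; adjusted p = 0.15 with an estimated correlation), growth factor signalling (−0.05, 0.15) and the xenobiotic response (−0.15, 0.30; CYP1A1 −0.71) also passed lower, each lost without control replicate 2 (0.08, 0.12 and 0.08) and at least 2 other arrays.

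Set directly against each other, androgen and estrogen differed in 0 of 8374 genes by limma, and 33 had an unadjusted p under 0.05 where 419 would by chance. Deviations of androgen replicates 1, 2 and 3 went with those of estrogen replicates 1, 3 and 2 (0.80, 0.83 and 0.68). A fit without a block counts these as spread and can miss differences, so the low count does not show that the hormones act alike. With a spike-in cluster block, which holds that pairing, 0 passed as well. The median gene differed by 0.07 log2 either way, and the lowest p values belonged to DNAAF8 (0.26), SH3D21 (0.42) and the collagen COL9A1 (0.30), none of which passed (adjusted p = 1). Mitosis (29 of 31 lower with androgen, median −0.10, adjusted p = 0.033) and DNA replication genes (33 of 36 lower, −0.13, adjusted p = 0.033) were below their level with estrogen. Neither held with an estimated correlation (adjusted p = 0.96 for both), mitosis was not past the threshold with scan day as a block (0.051), both fell short with a block for spike-in cluster (0.059), by which deviations of these arrays correlated at a mean of 0.77, or for replicate number (0.073), and within days 1, 3 and 4 the medians were −0.21, 0.19 and −0.30 for mitosis and −0.27, 0.27 and −0.34 for DNA replication (−0.21, −0.04 and −0.06, and −0.27, −0.07 and −0.07, within spike-in clusters). Both calls were lost without androgen replicate 1 (0.53 and 0.92), androgen replicate 3 (0.32 and 0.21) or estrogen replicate 3 (0.31 and 0.68), and mitosis also without estrogen replicate 1 (0.19).

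Across genes, which are not independent replicates, the androgen and estrogen changes correlated at r = 0.83. Unchanged groups that share the control arrays gave 0.50 in 100 simulations. The covariance was 0.0324 against a simulated 0.0206 and a highest simulated value of 0.0231. The simulation took deviations of the arrays as independent, but between androgen and estrogen arrays of the same spike-in cluster they correlated at a mean of 0.77, which adds covariance of its own, so the excess may come in part from batches. Leaving out single arrays gave r between 0.70 and 0.92.

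Letrozole raised 10 genes over androgen alone, and no gene fell past the threshold in a model without batches; with a block for spike-in cluster, chosen after seeing the data, 47 passed, 32 higher and 15 lower. The carbonic anhydrase CA2 rose most, from 309 ± 27.1 to 1840 ± 389 (log2 2.32 ± 0.30, adjusted p = 0.0025). SH3BGRL went from 712 ± 174 to 2520 ± 741 (1.72 ± 0.22), the secreted glycoprotein stanniocalcin 1 (STC1) from 407 ± 36.7 to 1490 ± 215 (1.71 ± 0.27), the actin-oxidising enzyme MICAL2 from 106 ± 4.82 to 435 ± 128 (1.51 ± 0.20), and MCCC2, a subunit of the leucine-degrading methylcrotonyl-CoA carboxylase, from 2360 ± 303 to 6970 ± 2200 (1.49 ± 0.21). The growth factor FGF18 (1.39), the peroxisomal acyltransferase CROT (1.25), the histone gene H4C8 (1.21), DNAAF1 (1.18) and myoglobin (MB, 0.74) made up the rest. The estrogen-induced genes PDZK1 (1920 ± 285 to 251 ± 158, −2.75 ± 0.66, adjusted p = 0.22), PGR (−0.94), TFF1 (−0.64), CXCL12 (−0.63) and GREB1 (−0.43) were lower without passing over all genes.

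These 10 genes were all higher and 0 lower, against 332 genes at an unadjusted p under 0.05 where 419 would come by chance. Of all genes, 617 (7.37%) had arrays of the groups fully apart, a share that is 10% by chance for 3 against 3. Deviations from the group mean correlated between letrozole and androgen arrays at a mean of 0.21 within spike-in clusters and 0.11 within replicate numbers. Androgen replicates 1, 2 and 3 went with letrozole replicates 1, 3 and 2 (0.50, 0.46 and 0.46), a pairing that neither block holds. Cluster 2 joins letrozole replicates 1 and 3, whose deviations correlated at −0.80. Deviations from a mean of 3 cancel out, so pairs within a group lean negative by construction (−0.59 and −0.00 for the other letrozole pairs). That lean also lowers the mean within clusters where a cluster holds more than 1 array of a group. The count was 47 with a spike-in cluster block, 12 (11 higher, 1 lower) with a replicate block and 10 with neither. A scan day block gave 14 genes. CA2, SH3BGRL, MICAL2, MCCC2, FGF18 and CROT passed whichever array was left out (adjusted p at most 0.039), whereas 6 genes in all passed without androgen replicate 3. Without that array STC1 had an adjusted p of 0.074 and H4C8 of 0.24, and without androgen replicate 2 DNAAF1 and MB both had 0.13. These 4 genes were each lost without at least 4 of the 6 arrays. With a pseudocount of 1 another probe set had the highest mean for MICAL2 and fell short (0.83, adjusted p = 0.49), while on the same probe set MICAL2 passed (1.99, adjusted p = 0.0022); H4C8 was lost (0.056). In a fit to only the 6 arrays compared, SH3BGRL (0.077), MCCC2 (0.087), CROT (0.09), H4C8 (0.087), DNAAF1 (0.17) and MB (0.23) fell short, while PDZK1 passed (adjusted p = 0.016).

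Letrozole lowered the estrogen-induced genes as a group at the preset correlation (29 of 35 lower, median −0.37, adjusted p = 5.6e-10; adjusted p = 0.14 with an estimated correlation). Adjusted over the list alone, 4 passed, all lower: PDZK1, the steroid receptor co-chaperone FKBP4 (−0.52), the small heat shock protein HSPB8 (−0.59) and the calcitonin receptor CALCR (−0.56). The list median was −0.26, −0.31 and −0.28 within days 1, 3 and 4 (adjusted p = 1.5e-10 with scan day as a block) and −0.46 and −0.25 within spike-in clusters 2 and 3, cluster 1 having no letrozole array. Interferon response genes rose (18 of 18, median 0.51, adjusted p = 6.1e-09; adjusted p = 0.38 with an estimated correlation), with medians of 0.09, 0.68 and 0.94 within those days and 0.24 and 0.74 within those clusters. Androgen receptor targets rose (7 of 8, 0.24, adjusted p = 0.0047; adjusted p = 0.11 with an estimated correlation), FKBP5 (0.46) and TSC22D3 (0.93) passing adjusted over the list alone. That call was lost without letrozole replicate 1 (0.096), and its medians were 0.20, 0.15 and 0.25 within days and 0.18 and 0.18 within clusters.

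Cholesterol biosynthesis genes fell with letrozole (12 of 16, median −0.14, adjusted p = 0.018; adjusted p = 0.61 with an estimated correlation), a call lost without androgen replicate 1 (0.068) and turned in direction without letrozole replicate 3 (0.95). Luminal epithelial markers rose (8 of 11, 0.13, adjusted p = 0.018; adjusted p = 0.33 with an estimated correlation), lost without letrozole replicate 1 (0.086) or 2 (0.2). Within days 1, 3 and 4 the medians were −0.06, −0.18 and −0.33 for cholesterol biosynthesis and 0.23, 0.27 and 0.06 for the luminal markers, and within clusters 2 and 3 −0.29 and −0.04, and 0.03 and 0.28. CD44 (−0.51) passed adjusted over the basal and mesenchymal list alone. MYC (−0.29 ± 0.51), MKI67 (0.13 ± 0.27), CCND1 (−0.24 ± 0.18) and ESR1 (0.17 ± 0.31) did not pass. Scan day as a block left these lists their calls, the highest adjusted p being 0.015.

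**Figure D2:**
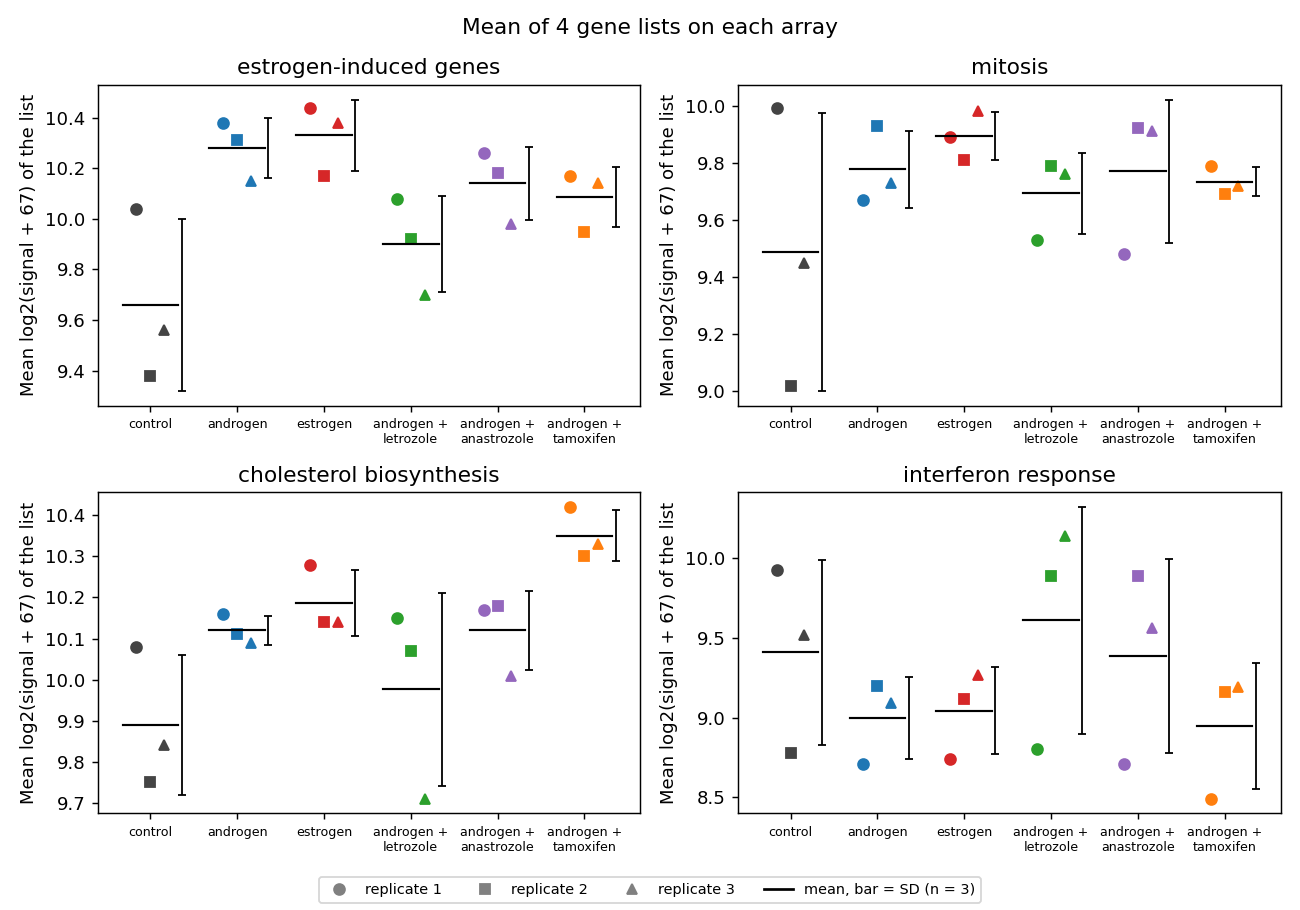
Mean log2(signal + 67) of the measured members of 4 gene lists on each array; points are arrays, and bars are the SD around the mean of 3. Estrogen-induced genes averaged 9.66 in control, 10.28 with androgen, 10.33 with estrogen and 9.90 with letrozole, and interferon response genes spread over 8.49 to 10.14 across arrays.

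For anastrozole against androgen no gene passed over the whole array. CA2 went from 309 ± 27.1 to 1310 ± 640 (1.75 ± 0.30, adjusted p = 0.06) and SH3BGRL from 712 ± 174 to 1930 ± 445 (1.36 ± 0.22, adjusted p = 0.052). ID1, an inhibitor of basic helix-loop-helix transcription factors, had the lowest p (923 ± 190 to 344 ± 108, −1.28 ± 0.20, adjusted p = 0.052). The 10 genes that rose with letrozole were all higher with anastrozole, by 0.56 to 1.75 with a median of 0.92, but they were chosen on the same androgen arrays, which favours that direction. Tamoxifen against those androgen arrays had 6 of the 10 higher (median 0.11), and anastrozole against control, which shares no array with the choice, all 10 (median 0.65), where 1, CA2, passed. PDZK1 (−1.44), PGR (−0.52), CXCL12 (−0.49), CCND1 (−0.18), TFF1 (−0.12), GREB1 (0.06), MYC (−0.24), ESR1 (0.12) and MKI67 (0.07) did not pass.

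With limma 0 genes passed for anastrozole against androgen, and 126 had an unadjusted p under 0.05. Counts of 2 to 6 came from other settings, the spike-in cluster block giving 4 (3 higher, 1 lower). Scan day as a block gave 6 genes, all higher, with CA2 at 2.22 (adjusted p = 0.0037) and SH3BGRL at 1.44 (0.01). Without anastrozole replicate 1, the array alone on its scan day, 6 genes also passed, with CA2 at 2.19 (adjusted p = 6.7e-04). The scan day block also takes out that array, so these settings are not separate checks. Without anastrozole replicate 3, 1 gene passed, ID1 (adjusted p = 0.013).

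Group shifts with anastrozole were small. Interferon response genes rose (17 of 18, median 0.35, adjusted p = 6.6e-05; adjusted p = 0.66 with an estimated correlation), and estrogen-induced genes fell (26 of 35, median −0.14, adjusted p = 0.0083; adjusted p = 0.66 with an estimated correlation). Luminal markers rose (10 of 11, 0.11, adjusted p = 0.0083; adjusted p = 0.25 with an estimated correlation), and basal and mesenchymal markers fell (4 of 6, −0.09, adjusted p = 0.0083; adjusted p = 0.16 with an estimated correlation), with CD44 (−0.57) passing adjusted over the list alone. Immediate early genes fell (16 of 18, −0.29, adjusted p = 0.0083; adjusted p = 0.67 with an estimated correlation), the growth-responsive factor KLF6 being at −0.45. Androgen receptor targets rose (6 of 8, 0.16, adjusted p = 0.013; adjusted p = 0.16 with an estimated correlation), as did unfolded protein and amino acid stress genes (14 of 19, 0.14, adjusted p = 0.029; adjusted p = 0.52 with an estimated correlation). With scan day as a block the last 2 lists did not pass (0.24 and 0.89).

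Within days 3 and 4, the only days that hold both anastrozole and androgen arrays, the medians were 0.59 and 0.34 for the interferon response, −0.05 and −0.11 for estrogen-induced genes, 0.13 and 0.17 for luminal markers, −0.34 and −0.15 for basal and mesenchymal markers, and 0.20 and −0.94 for immediate early genes. They were 0.04 and 0.31 for androgen receptor targets and 0.10 and 0.06 for stress genes. Within spike-in clusters 2 and 3 they were −0.08 and 0.75, −0.21 and 0.06, 0.12 and 0.20, −0.19 and −0.17, −0.03 and −0.54, 0.15 and −0.05, and 0.18 and 0.20 in that order. Every one of the 7 calls was lost without some array. The estrogen-induced and luminal calls were lost without anastrozole replicate 3 (adjusted p = 0.43 and 0.16), the interferon call without anastrozole replicate 2 (0.13), and the calls for immediate early genes and stress genes turned in direction without androgen replicate 3 (0.86) and anastrozole replicate 1 (0.75). Androgen receptor targets and basal markers were lost without anastrozole replicate 1 (0.17 and 0.08).

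**Figure D3:**
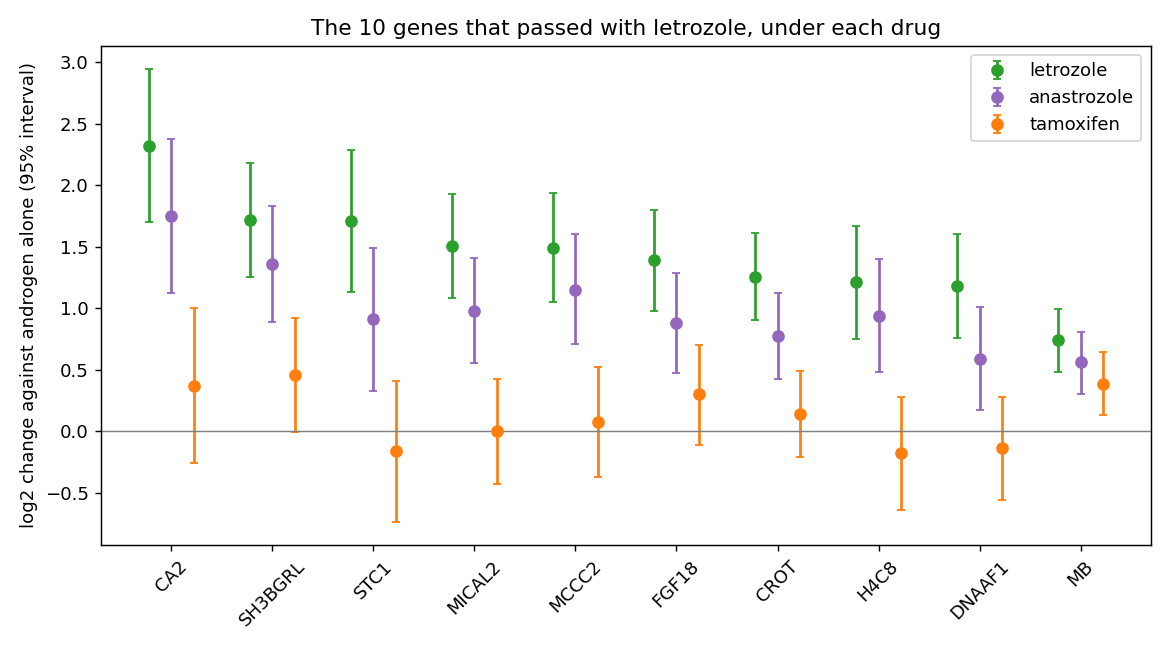
Log2 change against androgen alone of the 10 genes that rose with letrozole, for each of the 3 drugs; bars are 95% intervals. The genes were chosen on the letrozole comparison, and all 3 comparisons share the androgen arrays.

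Letrozole and anastrozole, compared directly, differed in 0 genes by limma, with 58 at an unadjusted p under 0.05 where 419 would be by chance. With a block for replicate number, by which deviations of these arrays correlated at a mean of 0.60, 0 passed as well. All 10 genes that rose with letrozole were higher with letrozole than with anastrozole, by 0.18 to 0.80, and 5 of them passed adjusted over those alone, but the genes were chosen on the same letrozole arrays, which favours both this direction and these calls in advance. The 95% interval of the difference was 0.22 to 1.38 for STC1, 0.14 to 0.84 for CROT, 0.10 to 0.95 for MICAL2, 0.10 to 0.92 for FGF18 and −0.10 to 0.78 for MCCC2. The lowest p values belonged to FKBP4 (1630 ± 127 with letrozole, 2200 ± 88.4 with anastrozole, −0.42), the spermine oxidase SMOX (0.53) and the kinase MAP2K2 (−0.35), none of which passed (adjusted p = 1). The median half-width of an interval was 0.32, so differences of that size remain open for most genes, and the labels do not say whether doses were matched.

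As groups, estrogen-induced genes were lower with letrozole than with anastrozole (29 of 35, median −0.19, adjusted p = 3.7e-08; adjusted p = 0.28 with an estimated correlation), a call lost without letrozole replicate 3 (0.15). Cholesterol biosynthesis was lower (15 of 16, −0.10, adjusted p = 0.0023; adjusted p = 0.51 with an estimated correlation) and turned in direction without that array (0.83). Growth factor signalling was higher (17 of 25, 0.06, adjusted p = 0.023; adjusted p = 0.28 with an estimated correlation) but was lost without any of 5 arrays, up to 0.3 without letrozole replicate 3. The interferon response was higher (17 of 18, 0.19, adjusted p = 0.0032; adjusted p = 0.75 with an estimated correlation), was lost with scan day as a block (0.37) and turned in direction without anastrozole replicate 1 (0.94). Both settings take out that array. Medians within days 3 and 4 were −0.22 and −0.24, −0.13 and −0.27, 0.08 and 0.11, and −0.01 and 0.51 in that order, and within spike-in clusters 2 and 3 −0.18 and −0.22, −0.10 and −0.13, 0.06 and 0.08, and 0.29 and −0.01. The responses to the inhibitors correlated at r = 0.78 against a simulated 0.50, with a covariance of 0.0229 against 0.0207 and a highest simulated 0.0223. That margin is small, and the simulation lacks the batches: both inhibitors have arrays in spike-in clusters 2, 3 and 2 and androgen in 1, 2 and 3, and deviations of same-number letrozole and anastrozole arrays correlated at 0.70, 0.71 and 0.40, so a shared response is not shown by it. Without anastrozole replicate 3 the correlation was 0.54.

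Tamoxifen raised a single named gene over androgen, the dermatan and chondroitin sulfotransferase UST (120 ± 10.8 to 237 ± 34.8, log2 0.70 ± 0.09, adjusted p = 0.0058). Of probe sets tested singly 8 passed (7 higher, 1 lower), 4 of them without a gene name and all 4 higher, with 209988_s_at (68.6 ± 13.8 to 2190 ± 492, 4.04, adjusted p = 1.4e-11) and 209987_s_at (3.54, adjusted p = 5.0e-10) far above UST. Among estrogen-induced genes PDZK1 (1920 ± 285 to 346 ± 164, −2.34 ± 0.66) and MYBL1 (762 ± 184 to 169 ± 77.8, −1.83 ± 0.38) were lower, while the LIM-domain cofactor FHL2 (608 ± 124 to 1180 ± 192, 0.89) and the trefoil peptide TFF3 (600 ± 90.7 to 1150 ± 437, 0.82) were higher. These 4 passed adjusted over the list alone. The list as a whole did not pass (16 higher, 19 lower, median −0.19, adjusted p = 0.095). PGR (0.07), GREB1 (0.25), TFF1 (−0.39), CXCL12 (−0.58), CCND1 (−0.26), ESR1 (0.02), MYC (−0.10) and MKI67 (−0.11) did not pass.

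Cholesterol biosynthesis genes rose with tamoxifen (14 of 16, median 0.18, adjusted p = 2.0e-05; adjusted p = 0.31 with an estimated correlation), led by the sterol reductase TM7SF2 (1190 ± 81.2 to 1880 ± 164, 0.62), which passed adjusted over the list alone. The list median was 0.26, 0.15 and 0.14 within spike-in clusters 1, 2 and 3 and 0.26, 0.10 and 0.22 within days 1, 3 and 4 (adjusted p = 3.4e-05 with scan day as a block), and the call held whichever array was left out. BIK (0.56), the insulin receptor substrate IRS2 (−0.49) and the lysosomal enzyme GUSB (−0.79) also passed adjusted over their own lists alone. Over all genes 210 had an unadjusted p under 0.05. UST was lost without androgen replicate 3 (adjusted p = 0.076), with the mean of its probe sets (0.46, adjusted p = 0.16) and with only the 6 arrays compared (0.14). Without tamoxifen replicate 1, 2 genes passed and without tamoxifen replicate 3, 4 did. A scan day block gave 5, MYBL1 (0.016) among them, and a spike-in cluster block 7 (5 higher, 2 lower).

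Letrozole and tamoxifen differed most among the drugs, in 13 genes higher and 12 lower with letrozole. The monoamine oxidase MAOB (1500 ± 411 against 247 ± 37.5, 2.29 ± 0.30, adjusted p = 0.0049), CA2 (1.95), STC1 (1.87), the adhesion molecule ALCAM (1.53) and MICAL2 (1.51) were the highest. The peptide-amidating enzyme PAM (292 ± 77.2 against 1230 ± 356, −1.83, adjusted p = 0.0054), the adenylyl cyclase ADCY1 (−1.68), ID2 (−1.24), FHL2 (−1.19) and the efflux transporter ABCG2 (−1.11) were the lowest. In anastrozole against tamoxifen 1 of the 25, MAOB, passed; both comparisons share the tamoxifen arrays on which the genes were chosen, so the direction of the others there tells little. Of the 25, 9 were among the genes that rose with letrozole over androgen.

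In that comparison 348 genes had an unadjusted p under 0.05, 33 passed with scan day as a block, 34 (16 higher, 18 lower) with a block for replicate number and 50 (24 higher, 26 lower) with a spike-in cluster block; deviations of these arrays correlated at a mean of 0.27 by number and 0.13 by cluster. Without letrozole replicate 2 or tamoxifen replicate 1, 12 passed. ALCAM was lost without letrozole replicate 2 (adjusted p = 0.084), ADCY1 (0.21) and ID2 (0.097) without tamoxifen replicate 1, and FHL2 without tamoxifen replicate 2 (0.26) and with scan day as a block (0.054). For ADCY1, 1 of 2 bright probe sets went this way, and the mean of its probe sets fell short (−0.57, adjusted p = 0.11). With a pseudocount of 1 FHL2 was lost (0.053), MICAL2 fell short on the other probe set then standing for it (0.87, adjusted p = 0.3) but passed on the same one (1.99, 0.004), and a fit to only the 6 arrays lost ALCAM (0.1), FHL2 (0.2) and ABCG2 (0.074).

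Cholesterol biosynthesis was lower with letrozole than with tamoxifen in 16 of 16 genes (median −0.33, adjusted p = 4.8e-11; adjusted p = 0.045 with an estimated correlation), and INSIG1, LSS, MSMO1, NSDHL and SQLE passed adjusted over the list alone. Its medians were −0.34, −0.17 and −0.50 within days 1, 3 and 4 and −0.40 and −0.17 within spike-in clusters 2 and 3. Androgen receptor targets were higher (7 of 8, 0.14, adjusted p = 0.0021; adjusted p = 0.045 with an estimated correlation), with medians of 0.28, 0.10 and 0.19 by day and 0.09 and 0.10 by cluster. Neither of these 2 lists passed with fry (adjusted p = 0.051 for both). Interferon response genes were higher (18 of 18, 0.56, adjusted p = 4.8e-11; adjusted p = 0.34 with an estimated correlation), with medians of 0.33, 0.77 and 0.67 by day and 0.22 and 0.77 by cluster. Estrogen-induced genes were lower (24 of 35, −0.25, adjusted p = 6.2e-04; adjusted p = 0.39 with an estimated correlation), with medians of −0.02, −0.10 and −0.33 by day and −0.35 and −0.10 by cluster, a call lost without letrozole replicate 3 (0.19).

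Anastrozole against tamoxifen gave 2 genes, both monoamine oxidases: MAOB (1590 ± 761 against 247 ± 37.5, 2.31 ± 0.30, adjusted p = 0.0071) and MAOA (565 ± 185 against 190 ± 14.6, 1.25 ± 0.19, adjusted p = 0.018). MAOA was lost without anastrozole replicate 2 (0.18), and both in a fit to only the 6 arrays compared (MAOB 0.078, MAOA 0.19). The count was 9 without anastrozole replicate 1, 1 without anastrozole replicate 2 and 6 without tamoxifen replicate 3, 8 with scan day as a block, 12 (7 higher, 5 lower) with a block for replicate number, by which deviations of these arrays correlated at a mean of 0.41 (0.13 by cluster), and 29 (14 higher, 15 lower) with a spike-in cluster block, with 203 genes at an unadjusted p under 0.05. Cholesterol biosynthesis was lower (16 of 16, −0.20, adjusted p = 4.9e-07; adjusted p = 0.16 with an estimated correlation) and the interferon response higher (17 of 18, 0.38, adjusted p = 4.9e-07; adjusted p = 0.45 with an estimated correlation). Stress genes (17 of 19, 0.19, adjusted p = 0.0023; adjusted p = 0.2 with an estimated correlation) and androgen receptor targets (6 of 8, 0.09, adjusted p = 0.016; adjusted p = 0.16 with an estimated correlation) were higher but not with scan day as a block (0.27 and 0.23) or without anastrozole replicate 1 (0.81 and 0.13). That block also takes out this array, the only one of its day, so these are not separate checks. The xenobiotic response was higher (10 of 12, 0.11, adjusted p = 0.046, and 0.47 with an estimated correlation), lost without anastrozole replicate 3 (0.85). With a block for replicate number 4 lists passed, against these 5 without it. Medians within days 3 and 4 were −0.13 and −0.23, 0.85 and 0.23, 0.11 and 0.10, −0.02 and 0.11, and 0.16 and 0.20 in that order, and within spike-in clusters 2 and 3 −0.27 and −0.13, −0.00 and 0.85, 0.26 and 0.11, 0.08 and −0.02, and −0.01 and 0.16.

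Against untreated control, letrozole with androgen raised 9 genes and lowered 1. CA2 was highest (249 ± 94.7 to 1840 ± 389, 2.62 ± 0.30, adjusted p = 0.0011), followed by TMEM164 (1.40), MCCC2 (1.27), MICAL2 (1.23) and CROT (1.17), and the annexin ANXA3 fell (259 ± 25.7 to 117 ± 47.3, −0.85, adjusted p = 0.04). CA2 held whichever array was left out, whereas TMEM164 and MCCC2 were lost without letrozole replicate 2 (both 0.16), and MICAL2 (0.15), CROT (0.083) and ANXA3 (0.29) without control replicate 3. ANXA3 was also lost with scan day as a block (0.054), quantile normalization (0.057), a pseudocount of 1 (0.069), no filter (0.05) or no trend (0.052), and MICAL2, with a pseudocount of 1, fell short on another probe set (0.89, adjusted p = 0.34) but passed on the same one (1.58, 0.03). In a fit to only the 6 arrays compared, TMEM164 (0.88), MCCC2 (0.7), MICAL2 (0.39), CROT (0.39) and ANXA3 (0.79) fell short. The count was 1, 2 and 6 without letrozole replicates 1, 2 and 3, and 19, 6 and 2 without control replicates 1, 2 and 3, with 252 genes at an unadjusted p under 0.05, 12 with scan day as a block and 23 (18 higher, 5 lower) with a spike-in cluster block. Mitosis was higher (31 of 31, 0.20, adjusted p = 7.1e-07; adjusted p = 0.57 with an estimated correlation), lost without control replicate 2 (0.98). Estrogen-induced genes were higher (24 of 35, 0.16, adjusted p = 0.0036; adjusted p = 0.57 with an estimated correlation), estrogen-repressed genes lower (10 of 12, −0.22, adjusted p = 0.014; adjusted p = 0.57 with an estimated correlation) and DNA replication higher (31 of 36, 0.10, adjusted p = 0.023; adjusted p = 0.66 with an estimated correlation). These 3 were lost without control replicate 2 (0.5, 0.4 and 0.83, the last turning in direction). Medians within days 1, 3 and 4 were −0.37, 0.75 and 0.28 for mitosis, 0.01, 0.54 and −0.02 for estrogen-induced genes, −0.08, −0.27 and −0.25 for estrogen-repressed genes and −0.69, 0.55 and 0.36 for DNA replication. Within spike-in clusters 2 and 3 all 4 turned: −0.39 and 0.32, −0.17 and 0.28, 0.06 and −0.27, and −0.46 and 0.34.

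Anastrozole with androgen raised CA2 over control (249 ± 94.7 to 1310 ± 640, 2.04 ± 0.30, adjusted p = 0.026) and lowered ID1 (914 ± 55.8 to 344 ± 108, −1.29 ± 0.20, adjusted p = 0.026). CA2 was lost without anastrozole replicate 2 (0.22), and ID1 without control replicate 3 (0.25) and with scan day as a block (0.096). Both fell short in a fit to only the 6 arrays compared (0.85 and 0.84). The count was 0 without anastrozole replicate 2, control replicate 2 or control replicate 3, 6 without anastrozole replicate 3 13 without control replicate 1 and 15 (13 higher, 2 lower) with a spike-in cluster block, with 270 genes at an unadjusted p under 0.05. Estrogen-induced genes were higher (31 of 35, 0.37, adjusted p = 9.0e-15; adjusted p = 0.083 with an estimated correlation), as were mitosis (31 of 31, 0.28, adjusted p = 2.7e-11; adjusted p = 0.31 with an estimated correlation) and cholesterol biosynthesis (15 of 16, 0.23, adjusted p = 1.7e-06; adjusted p = 0.13 with an estimated correlation). Lower were estrogen-repressed genes (−0.27; adjusted p = 0.25 with an estimated correlation), immediate early genes (−0.30; adjusted p = 0.55 with an estimated correlation), growth factor signalling (−0.07; adjusted p = 0.13 with an estimated correlation) and apoptosis regulators (−0.16; adjusted p = 0.13 with an estimated correlation). Mitosis was lost without control replicate 2 (0.15), and estrogen-repressed genes (0.073), growth factor signalling (0.16), apoptosis regulators (0.086) and immediate early genes (0.87, turning in direction) without control replicate 3. Medians within days 3 and 4 were 0.65 and 0.28 for estrogen-induced genes, 0.85 and 0.47 for mitosis, 0.39 and 0.24 for cholesterol biosynthesis, −0.31 and −0.48 for estrogen-repressed genes, 0.15 and −1.08 for immediate early genes, −0.17 and −0.18 for growth factor signalling, and −0.01 and −0.24 for apoptosis regulators. By spike-in clusters 2 and 3 they were 0.05 and 0.47, −0.32 and 0.43, 0.07 and 0.34, 0.07 and −0.39, −0.01 and −0.82, 0.01 and −0.17, and −0.27 and −0.11 in that order.

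With tamoxifen and androgen together, cholesterol biosynthesis rose over untreated control in 16 of 16 genes, by a median of 0.46 (adjusted p = 5.4e-19; with an estimated correlation adjusted p = 0.011; with fry adjusted p = 0.015). Adjusted over the list alone, 9 members passed: ACAT2, DHCR7, IDI1, INSIG1, LSS, MSMO1, MVD, NSDHL and SQLE. The median was 0.35, 0.52 and 0.47 within days 1, 3 and 4 and 0.74, 0.25 and 0.49 within spike-in clusters 1, 2 and 3. Estrogen-induced genes were higher (26 of 35, 0.29, adjusted p = 1.5e-13; adjusted p = 0.059 with an estimated correlation), with 8 passing adjusted over the list alone, among them PGR, GREB1 and TFF3, and medians of 0.26, 0.54 and 0.57 by day and 0.66, 0.05 and 0.38 by cluster. With limma 0 named genes passed, though 6 unnamed probe sets did when probe sets were tested singly, and 308 had an unadjusted p under 0.05, the lowest being UST (0.51, adjusted p = 0.17), SPINK4 (0.96, 0.17) and the adenosine receptor ADORA1 (1.41, 0.18). Unnamed probe sets may share a gene or measure a known gene, even a list member, so 6 is no count of genes. The count was 3 without tamoxifen replicate 3, 9 without control replicate 1 4 with scan day as a block, ADORA1 (0.029) among them, and 6 (5 higher, 1 lower) with a spike-in cluster block.

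The other lists that passed in tamoxifen against control did so at the preset correlation only. The interferon response was lower (18 of 18, −0.42, adjusted p = 2.0e-06; adjusted p = 0.34 with an estimated correlation), with medians of −1.58, 0.39 and −0.30 within days 1, 3 and 4. Mitosis (30 of 31, 0.26; adjusted p = 0.34 with an estimated correlation) and DNA replication (32 of 36, 0.15; adjusted p = 0.63 with an estimated correlation) were higher, both lost without control replicate 2 (0.62 and 0.83), with medians of −0.22, 0.68 and 0.31 and of −0.45, 0.46 and 0.48. The xenobiotic response (−0.23; adjusted p = 0.17 with an estimated correlation), growth factor signalling (−0.09; adjusted p = 0.13 with an estimated correlation) and estrogen-repressed genes (−0.21; adjusted p = 0.34 with an estimated correlation) were lower, the last 2 lost without control replicate 2 (0.11 and 0.13). Apoptosis regulators (−0.12; adjusted p = 0.16 with an estimated correlation) and immediate early genes (−0.26; adjusted p = 0.63 with an estimated correlation) were lower too, lost without control replicate 3 (0.1 and 0.45, the latter turning in direction). Medians within the days were −0.49, −0.22 and 0.12, −0.08, −0.11 and −0.26, −0.06, −0.25 and −0.40, −0.27, 0.03 and −0.22, and −0.21, 0.63 and −1.36 in that order. Within spike-in clusters 1, 2 and 3 they were −0.25, −0.57 and −0.31 for the interferon response, 0.71, −0.29 and 0.21 for mitosis, 0.41, −0.19 and 0.23 for DNA replication, −0.33, −0.20 and −0.12 for the xenobiotic response, −0.24, 0.02 and −0.16 for growth factor signalling, −0.46, 0.02 and −0.30 for estrogen-repressed genes, −0.14, −0.27 and −0.08 for apoptosis regulators and −0.13, 0.02 and −0.62 for immediate early genes.

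The drugs' opposition to the estrogen response was measured across genes, which are not independent replicates. The letrozole change against androgen correlated with the estrogen change against control at r = −0.47, with −0.22 for anastrozole and −0.21 for tamoxifen. Within replicate numbers 1, 2 and 3 the values were −0.01, −0.18 and 0.28 for letrozole, 0.07, 0.05 and 0.38 for anastrozole and −0.21, −0.21 and 0.51 for tamoxifen. Batches can raise these values. Same-number estrogen and drug arrays shared deviations (mean 0.52 for letrozole, 0.57 for anastrozole and 0.54 for tamoxifen). Same-number pairs with a control or androgen array mostly did not (5 of 27 over 0.1, mean −0.07). Androgen replicate 1 was an exception, going with the estrogen and drug arrays numbered 1 (0.50 to 0.80). The values by number therefore cannot decide whether the opposition repeats. As 0 genes passed for estrogen, the planned share of called genes that a drug reversed has no value. Of the 100 genes of lowest p for estrogen, chosen after seeing that count, 86 went the opposite way with letrozole, 74 with anastrozole and 73 with tamoxifen, where the shares over all 8374 genes were 59.9%, 51% and 49.1%. Tested with fry and adjusted over the 3 drugs, none passed (adjusted p = 0.13, 0.35 and 0.29). Without anastrozole replicate 3 its correlation was −0.03. The letrozole and tamoxifen changes correlated at 0.41 and the anastrozole and tamoxifen changes at 0.45, against a simulated 0.50 from the shared androgen arrays alone.

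A few groups did not pass in any comparison. The lowest adjusted p was 0.082 for cell cycle inhibitors and p53 targets, 0.18 for hypoxia and glycolysis, 0.19 for ribosome biogenesis, 0.21 for steroid metabolism enzymes, 0.26 for fibroblast and leukocyte markers and 0.44 for housekeeping genes.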

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

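The tests of spike-in levels by scan day, of degraded RNA, of excess in a batch and of a mislabelled sample were chosen after the result was seen. The tests on dim genes and on other splits of the arrays were chosen before. The spike-in clusters used for the dim genes, however, were chosen after seeing the data.

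Probe sets without a gene name in the annotation lie outside the gene tests and showed the largest differences of the series. Probe set 209988_s_at was 4.08 log2 units higher with tamoxifen and androgen than in control (2190 ± 492 against 64.7 ± 9.37, n = 3, adjusted p = 1.2e-11), and 209987_s_at was 3.72 higher (1730 ± 388 against 66.8 ± 5.23, adjusted p = 2.3e-10). With androgen alone they were at 68.6 ± 13.8 and 86.3 ± 28.7.

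Spike-in levels, which the comparisons do not use, lay nearest to the mean of another scan day on 4 of 6 control and androgen arrays, against 2 of 11 arrays of the other groups. Apart from androgen replicate 1, control and androgen arrays also deviated from their group's mean most closely with arrays of another replicate number. Among the other 4 groups, 18 of 18 same-number pairs correlated over 0.1. Numbers that do not follow the scan day are left open, since the count of 4 is the observation itself and cannot support them. A batch reaching genes near background would predict that, over 3589 dim genes, deviations of control and androgen arrays correlate more within spike-in clusters (0.25) than within replicate numbers (−0.04), and the difference was 0.30. A technical account therefore remains, and a biological one was not tested.

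Control replicate 1 lay above the other control arrays on the 35 estrogen-induced genes (mean log2 10.04 against 9.38 and 9.56, an excess of 0.57). Degraded RNA is argued against by its GAPDH 3' to 5' log2 ratio of −0.02, inside the range of the other 17 arrays (−0.19 to 0.17). A batch effect of its spike-in cluster that also acts in hormone-treated cells is argued against. In 5 other groups, all given androgen or estrogen, arrays of that cluster exceeded arrays of other clusters by a mean of 0.02 (SE 0.03, from −0.06 to 0.08). A batch effect confined to untreated cells could not show there, and batches by scan day or replicate number were not tested. A hormone-treated sample in its place stays open: 10.04 lies close below the lowest androgen or estrogen array (10.15, SD 0.12), and over 100 genes outside that list, picked without it, its position between hormone arrays (0) and the other control arrays (1) was 0.11, where 6 hormone arrays placed alike lay at −0.12 to 0.23 and the other controls at 0.95 and 0.63. Against it run single genes, which exclude nothing alone, such as MAOA (251; other controls 273 and 178, hormone arrays 373 to 518), SH3BGRL (1300; 1580 and 1400, 512 to 1030) and PGR (99.3, at least 138), and differences between untreated cultures, untested, would place it alike.

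Each comparison of 6 arrays allows 10 splits into 3 and 3, too few for a share under 0.05. Splits giving at least as many genes as the real groups, with the real count and the highest other count, were 10 for androgen against control (0, 0), 10 for estrogen against control (0, 0), 1 for letrozole against androgen (10, 0), 10 for anastrozole against androgen (0, 0), 1 for tamoxifen against androgen (1, 0) and 10 for androgen against estrogen (0, 0). They were 10 for letrozole against anastrozole (0, 4), 1 for letrozole against tamoxifen (25, 0), 1 for anastrozole against tamoxifen (2, 0), 1 for letrozole against control (10, 1), 2 for anastrozole against control (2, 64) and 10 for tamoxifen against control (0, 0). The split with 64 genes set anastrozole replicate 1 and control replicates 2 and 3 against the rest, which is the real grouping with the replicates numbered 1 exchanged; its cause was not tested, and treatment is not excluded while control replicate 1 stays in doubt.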

How the results depend on the processing

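Centring array medians and a robust fit changed no gene count by more than 1.5 times. The cause was not tested for any change given here, except where fewer arrays, fewer genes or a minimum fold make the test stricter by construction. The spike-in cluster block was chosen after seeing the data, as were the scan day block and the omission of arrays for gene lists. Over all groups 23 of 45 same-number pairs of arrays correlated over 0.1 (from −0.51 to 0.80), and 12 of 18 arrays went best with their own number. The numbers paired among letrozole, anastrozole, tamoxifen and estrogen (18 of 18 pairs over 0.1, mean 0.49) but mostly not with control or androgen arrays (5 of 27, mean −0.07). Androgen replicates 1, 2 and 3 went best with numbers 1, 3 and 2, and control replicates 1, 2 and 3 with numbers 3, 1 and 2. The spike-in clusters hold that pairing except for letrozole and anastrozole replicates 1, and no block fitted holds all of it.

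Genes passing in androgen against control were 2 with the replicate block, 1 with the scan day block and 0 with the spike-in cluster block. In estrogen against control they were 6, 3 and 0. Letrozole against androgen gave 16 with quantile normalization and 47 (32 higher, 15 lower) with the spike-in cluster block. Anastrozole against androgen gave 3 with quantile normalization, 2 with a pseudocount of 1 (0 on the same probe sets and genes), 3 without the lowest 50% of genes, 3 with the replicate block, 6 with the scan day block, 2 without the trend, 4 with the mean of the probe sets and 4 with the spike-in cluster block. Tamoxifen against androgen gave 5 with no filter, 0 without the lowest 50%, 5 with the replicate block, 5 with the scan day block, 4 with every probe set, 7 with the spike-in cluster block, 0 with a 2-fold minimum and 0 with only the 6 arrays compared. Letrozole against tamoxifen gave 50 (24 higher, 26 lower) with the spike-in cluster block, 16 with a 2-fold minimum and 10 with only the 6 arrays. Anastrozole against tamoxifen gave 4 with a pseudocount at the 40th percentile, 5 with no filter, 4 without the lowest 50%, 12 with the replicate block, 8 with the scan day block, 5 with the mean of the probe sets, 6 with every probe set, 29 (14 higher, 15 lower) with the spike-in cluster block and 0 with only the 6 arrays. Letrozole against control gave 6 without the lowest 50%, 16 with the replicate block, 23 with the spike-in cluster block and 1 with only the 6 arrays. Anastrozole against control gave 7 with the replicate block, 15 with the spike-in cluster block and 0 with only the 6 arrays. Tamoxifen against control gave 3 with no filter, 4 with the replicate block, 4 with the scan day block, 1 with every probe set and 6 with the spike-in cluster block.

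For estrogen-induced genes the adjusted p in letrozole against androgen was 0.14 with an estimated correlation and 0.19 with fry, and in anastrozole against androgen 0.66 and 0.94. ESR1 in tamoxifen against androgen was −0.01 with quantile normalization and −0.03 with the mean of the probe sets, and MKI67 0.00 with the latter.

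Leaving out each array gave 0 to 22 genes for androgen against control, 0 to 79 for estrogen against control, 6 to 9 for letrozole, 0 to 6 for anastrozole and 0 to 4 for tamoxifen against androgen, 12 to 20 for letrozole and 1 to 9 for anastrozole against tamoxifen, and 1 to 19, 0 to 13 and 0 to 9 for letrozole, anastrozole and tamoxifen against control. The similarity of the letrozole and anastrozole responses ranged from 0.54 to 0.84, and the opposition by anastrozole from −0.35 to −0.03. Changes in log2 that turned in direction ranged, for MYC, from −0.50 to 0.34 with androgen and −0.31 to 0.51 with estrogen against control, and from −0.68 to 0.12, −0.58 to 0.16 and −0.44 to 0.29 with letrozole, anastrozole and tamoxifen against androgen. In the same order MKI67 ranged from −0.01 to 0.30, −0.07 to 0.38, −0.05 to 0.32, −0.05 to 0.26 and −0.46 to 0.08. ESR1 ranged from −0.05 to 0.47, −0.10 to 0.42 and −0.29 to 0.32 with the 3 drugs against androgen, TFF1 from −0.27 to 0.12 and GREB1 from −0.14 to 0.28 with anastrozole, and PGR from −0.22 to 0.29 with tamoxifen.

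Adjusted p ranged from 2.5e-08 to 0.84 for DNA replication in androgen against control, 3.1e-04 to 0.95 for cholesterol biosynthesis in letrozole against androgen, and, in anastrozole against androgen, 4.8e-04 to 0.43 for estrogen-induced genes, 0.0012 to 0.75 for stress genes and 3.6e-04 to 0.86 for immediate early genes. In letrozole against anastrozole it ranged from 1.4e-06 to 0.83 for cholesterol biosynthesis and 8.3e-10 to 0.94 for the interferon response. Against control it ranged from 2.1e-09 to 0.83 for DNA replication with letrozole, and for immediate early genes from 3.8e-05 to 0.87 with anastrozole and 0.0011 to 0.45 with tamoxifen.

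Among 64 other list calls, all in their main direction, 61 fell short with an estimated correlation and 63 with fry, 3 with the replicate block, 6 with the scan day block, 11 with the spike-in cluster block, 4 with quantile normalization and 3 with centred medians. Over all omissions of an array 268 list results kept their call, 107 fell short and 9 turned. For named genes 671 kept theirs, 67 fell short, 18 newly passed and 30 turned.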

Other observations

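Metallothioneins, small metal-binding proteins, moved together, a set chosen after seeing the data. All 6 tested members (MT1E, MT1F, MT1H, MT1HL1, MT1X and MT2A) were higher with androgen than in control (median 0.62, camera p = 1.0e-08; p = 0.022 with an estimated correlation) and with estrogen (0.72; p = 0.024 with an estimated correlation). All 6 were lower with tamoxifen than with androgen alone (median −0.98, from −1.44 to −0.24, camera p = 1.5e-15; p = 0.0032 with an estimated correlation), while letrozole (−0.22) and anastrozole (0.08) left them nearer to the androgen level. Against tamoxifen they were higher with anastrozole (1.09; p = 0.0015 with an estimated correlation) and letrozole (0.70; p = 0.017 with an estimated correlation, but 0.092 without letrozole replicate 1 and 0.058 without tamoxifen replicate 2). Single arrays carried much of the rise with hormones: MT2A was 11200 on androgen replicate 2 (6100 and 5150 on the others) and 11200 on estrogen replicate 3 (6000 and 4940), against 3920, 4090 and 1970 in control, and MT1X 4710 (2350 and 2270) and 5150 (2730 and 2410), against 2030, 2060 and 1280; both arrays belong to spike-in cluster 2. Without them the medians were 0.41 (p = 0.1 with an estimated correlation) and 0.43 (p = 0.098), and without control replicate 3 0.43 (p = 0.11) and 0.49 (p = 0.073); without control replicate 1 p was 0.076 and 0.098. The median for tamoxifen against androgen stayed between −1.12 and −0.70 whichever array was left out (p at most 0.021 with an estimated correlation). No member passed singly over all genes, and these p-values are not adjusted for the choice.

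Over 15550 probe sets tested singly, 7 passed in tamoxifen against control, 6 of them without a gene name, and 8 in tamoxifen against androgen, 4 of them without a name. Several probe sets can measure the same gene, so these are not counts of genes. Probe set 210139_s_at, also unnamed, was lower than control with anastrozole (5270 ± 3210 to 503 ± 222, log2 −3.14, adjusted p = 0.0094) and with letrozole (−2.51, adjusted p = 0.026).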
